A study of Rattus norvegicus with 6 samples.

How the data were processed

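Hearts of male Dahl S rats and of male S.LEW congenic rats were profiled on 6 Affymetrix Rat Expression Array 230 2.0 chips, 3 per strain. Per the labels, each chip carried RNA pooled from 2 animals, so that 6 animals stood behind each strain, and 15 µg of biotin-labelled cRNA, prepared from 6 µg of total RNA, was hybridized to each chip. The authors summarised the arrays with RMA, per the submitters' processing notes, and the deposited values were log2 expression per probe set, already background-corrected and normalized between arrays. The version of RMA and the probe annotation behind it were not given in the sources used here. The study's own statistics, per the series' design text, used Benjamini-Hochberg adjustment in R 2.8.1.

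The deposited log2 values were used without further normalization. Of 31099 probe sets on each array, the 57 Affymetrix control probe sets were set aside and 31042 were tested. The platform annotation, with symbols updated through the rat RefSeq table of assembly GRCr8, gave 20826 probe sets exactly 1 gene, 436 several genes and 9780 no gene. Probe sets with several genes or none were tested and are unnamed here. For tests on genes, the probe set with the highest mean over all arrays stood for its gene, which left 14217 genes, 14167 of them with a chromosome. The GRCr8 table served for names and for the order of neighbouring genes, and no coordinate was taken from it.

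The strains were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, strain as the only term), as congenic minus Dahl S, with Benjamini-Hochberg adjustment over the 31042 probe sets and a call at an adjusted p under 0.05. Gene lists, 29 in all with 584 of their 692 genes measured, were tested with limma's camera at a preset correlation of 0.01 and adjusted over the 29 lists. Camera with a correlation estimated per list and limma's fry were the alternatives. Shares of genes with an unadjusted p under 0.05 were compared by Fisher's exact test, two-sided, for chromosome 10 against all other chromosomes and for the 20 measured genes on each side of Rffl against all other genes. These tests treat genes as independent, which neighbouring genes need not be. Intervals are at 95% confidence. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

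The tests, the gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule named Rffl and the called members of its chromosome 10 list, and the 10 genes higher and the 10 lower with the largest change among called probe sets with 1 gene. Where fewer than 10 in a direction passed, it filled up with the genes of smallest unadjusted p among probe sets brighter than the median probe set, which are reported as not passing. It also named the 2 members of each list with the smallest unadjusted p, any called members up to 4, and Nppa, Nppb, Myh6 and Myh7 in any case. Beyond the rule, Stard6, Rab27b, Dcc, Ccl2, Ccl4, Ccl6, Tefm, Isg15, Mx2, Gbp2, Cxcl10, Usp18, Mx1, Psmb8, Mki67, Ube2c, Loxl1, Bgn, Timp1, Scn4b, Cd3e, Ms4a1, Ptprc, Plin1 and Adipoq were chosen after their values had been seen.

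On simulated data built from these arrays, in 5 runs with 200 of the 31042 probe sets changed, the strain test recovered 84.5% of changes of 0.5 on the log2 scale, 99.1% of changes of 1 and 100% of changes of 1.5. Of its 1015 calls, 68 (6.70%) fell on probe sets that had not been changed. These shares hold for 200 changed probe sets and for noise drawn from the moderated variances, independently for each probe set. The fit to the real arrays made 11 calls, which sets a stricter cutoff. There no called probe set differed by less than 0.59 and Stard6, at 0.97, did not pass, so the shares do not give the sensitivity of that fit. In the same runs, over 14217 genes, a list shifted by 0.25 was called in 5 of 5 runs, and 4 calls in all fell on lists that had not been shifted themselves but could share genes with the shifted list. Because the simulated genes were independent, these runs do not show how often the list test calls unshifted lists of correlated genes. On the real arrays the correlation estimated per list ran from -0.036 to 0.749. The adjusted p rose with the estimated setting even for lists whose estimate lay near or below the preset 0.01. The gap between both settings is thus not a measure of correlation alone.

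Pearson correlations between arrays ran from 0.993 to 0.998 over the tested probe sets, and 0 arrays were identical. Each array was a separate pool of animals, and the number of arrays limits the precision. The replicate numbers in the labels are shared by the strains, but nothing ties a number to a cage or a day. The hybridization-control probe sets, which read bacterial and bacteriophage transcripts spiked into each sample, had a mean log2 level of 11.54 on Dahl S array 3 and 11.55 on congenic array 2 against 10.67 to 10.83 on the other 4 arrays. Because each strain had 1 array at the high level, this level was examined as a possible batch after the data had been seen.

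The alternatives were quantile normalization, median centring, leaving out dim probe sets or those without exactly 1 gene, eBayes with a trend or with robust priors, the ordinary variance without moderation, array weights, the replicate number as a block, leaving out each array in turn, a fold threshold of 1.5, an adjusted p under 0.1, the mean of a gene's probe sets, an unadjusted p under 0.01 and 10 genes on each side of Rffl. In the robust and ordinary-variance settings, the lists were tested with the preranked form of camera on the z-transformed test statistics. Added after the data had been seen were the hybridization-control level as a block, the 4 arrays of low level alone, the count without the probe sets of Mbd2, Stard6 and C18h18orf54, and the share around Rffl without Ccl5.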

Results

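Cardiac gene expression was measured in young male rats of a pair of related strains. The Dahl S rat is an inbred strain that becomes hypertensive on dietary salt. The congenic strain, S.LEW(10)x12x2x3x5, has the Dahl S background with a segment of chromosome 10 from the Lewis (LEW) rat. All animals were born on the same day, weaned at 30 days, kept on a low-salt diet (0.3%) and killed at 53 days of age. Each strain gave 3 arrays, each of RNA pooled from the hearts of 2 rats. The comparison asked which cardiac transcripts differ between the congenic and the Dahl S heart, and whether genes around Rffl on chromosome 10 are among them. The extent of the Lewis segment is not given in the sources used here, so Rffl, the gene on which published work on this strain has centred, and the 20 measured genes on each side stood in for it. Differences are given as congenic minus Dahl S on the log2 scale.

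Among called probe sets with 1 gene, the largest differences lay on chromosome 18. Mbd2, which encodes a protein that binds methylated DNA and recruits a repressor complex, rose from 10.90 ± 0.05 to 12.31 ± 0.05 (log2 expression, SD, n = 3 each; limma adjusted p = 4.06e-04), a 2.65-fold difference (log2 1.40, SE 0.06). C18h18orf54, a protein-coding gene of little-known function 2 measured genes away, rose 3.59-fold on 1 probe set (log2 1.85, SE 0.10, adjusted p = 9.88e-04) and 2.91-fold on the other (log2 1.54, SE 0.07, adjusted p = 5.60e-04). Stard6, which encodes a lipid transfer protein of the START family and lies between them in annotation order, was 1.95-fold higher and did not pass (log2 0.97, SE 0.11, adjusted p = 0.0597). With 1 array left out its log2 difference ran from 0.88 to 1.08 and its adjusted p from 0.0210, without congenic array 3, to 0.430. It was singled out after its values had been seen. In all 4 probe sets of these genes every congenic array lay above every Dahl S array. The measured genes on either side of the group, Rab27b and Dcc, had log2 differences of -0.03 and -0.02. Among the 38 other measured genes within 20 of Mbd2 on either side, the log2 differences ran from -0.22 to 0.17 with a median of -0.02. Limma called 0 of these 38 genes, and 4 had an unadjusted p under 0.05.

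**Figure D1:**
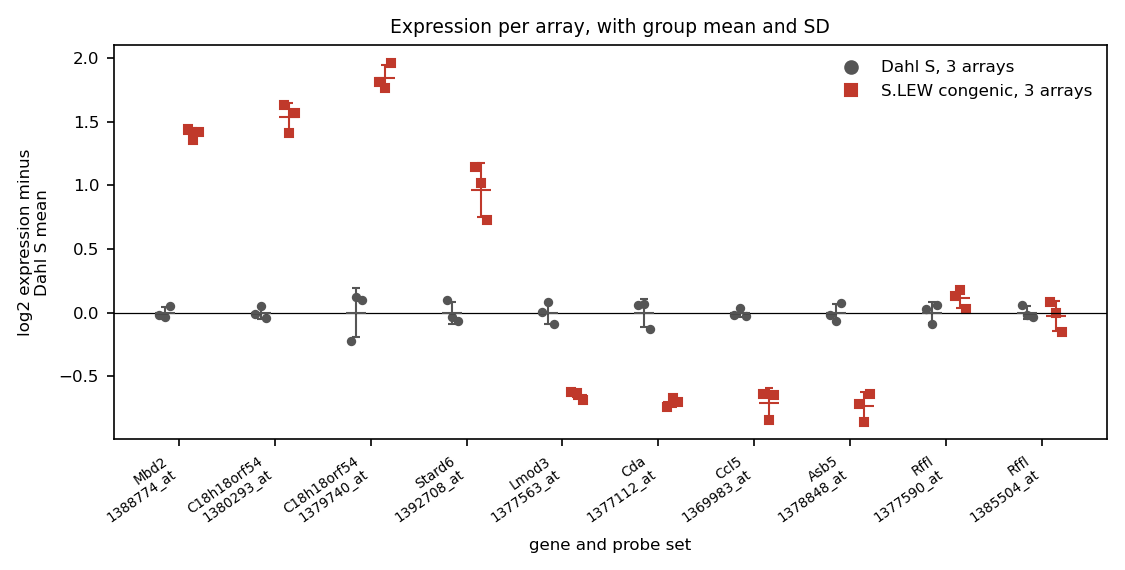
Log2 expression on each array minus the Dahl S mean, for the probe sets of the called genes, Stard6 and Rffl. Grey circles are the 3 Dahl S arrays and red squares the 3 congenic arrays, with a dash and bar for each group's mean and SD. The congenic arrays lie above the Dahl S arrays for Mbd2, C18h18orf54 and Stard6, lie below them for Lmod3, Cda, Ccl5 and Asb5, and overlap with them for Rffl.

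Another 4 named genes fell in the congenic heart. Ccl5, a chemokine that attracts T cells, fell by 0.71 (SE 0.07, 1.63-fold), and it was the only named gene of chromosome 10 that was called. Cda, the cytidine deaminase of pyrimidine salvage, fell by 0.70 (SE 0.07, 1.63-fold). Lmod3, which nucleates actin filaments in striated muscle, fell by 0.65 (SE 0.06, 1.56-fold), while its dimmer probe set differed by -0.20 (adjusted p = 0.731). Asb5, an ankyrin-repeat protein known from skeletal muscle, was called on a probe set so dim, with means of 4.38 in Dahl S and 3.64 in the congenic heart, that no fold is given. Its brighter probe set differed by -0.31 and did not pass (adjusted p = 0.729). The 4 called probe sets had an adjusted p of 0.0366 in limma, and in each the congenic arrays lay below all Dahl S arrays. These 4 calls were less secure than those on chromosome 18. With 1 array left out, the adjusted p ran from 0.133 to 0.273 for Ccl5, from 0.0220 to 0.269 for Cda, from 0.0543 to 0.264 for Lmod3 and from 0.0982 to 0.264 for Asb5. Mbd2 passed in each of these fits, with an adjusted p of at most 0.00643. With the probe sets of Mbd2, Stard6 and C18h18orf54 left out, limma called 3 probe sets, and the calls on Ccl5, Cda, Lmod3 and Asb5 were lost.

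In total, limma called 11 of the 31042 probe sets, 6 higher and 5 lower in the congenic heart, and 7 of the 11 carry the 6 gene names above. Of the 4 that are unnamed here, 3 were higher, among them 1388630_at (log2 1.48, 2.80-fold) and 1393094_at (log2 1.31, 2.47-fold), and 1 was lower, 1384247_at (log2 -0.59, 1.51-fold). These 4 have no chromosome in the annotation used, so whether any lies beside Mbd2 is not known here. At an unadjusted p under 0.05 there were 2071 probe sets, 1108 higher and 963 lower, where 1552.1 would be expected by chance. This number was 3131 without Dahl S array 1, and it was below that expectation without Dahl S array 2 (1538) or congenic array 2 (1448). The count of 11 fell to 5 or 6 with any 1 array left out and to 0 with the ordinary variance in place of limma's moderated one. Within the 4 arrays of low hybridization-control level it was 2. With that level as a block it was 5. Within those 4 arrays and between the 2 of high level, the mean difference of the 4 chromosome 18 probe sets was 1.47 and 1.38, and that of Ccl5 was -0.65 and -0.82.

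Below the threshold, the genes next in line included Nmrk2, a nicotinamide riboside kinase of muscle, with a log2 difference of 0.48 (adjusted p = 0.0597), and Inha, the inhibin alpha subunit, with 0.61 (adjusted p = 0.0718). The others on the higher side were the interferon-induced Irf7 (0.46) and Ifit3 (0.47), the mitotic genes Cdca3 (0.35) and Prc1 (0.50), Rps4y2 (0.44) and Fam98a (0.29), with adjusted p from 0.307 to 0.523. On the lower side were Ano5, an anoctamin linked to muscle disease (-0.65, adjusted p = 0.126), Ankrd45 (-0.50), the sodium channel gene Scn1a (-0.50), the connexin gene Gja3 (-0.39), Inhca (-0.43) and Cds1, a CDP-diacylglycerol synthase (-0.65), the last 5 with adjusted p from 0.189 to 0.315. The classical markers of cardiac load did not pass either. Nppa differed by 0.04, Nppb by 0.23, Myh6 by -0.02 and Myh7 by 0.29, with adjusted p from 0.736 to 0.966. Nppb differed by 0.11 without Dahl S array 1 and Myh7 by 0.19 without Dahl S array 3, and with 1 array left out Nppa ran from 0.02 to 0.06 and Myh6 from -0.03 to 0.00. Within the 4 arrays of low hybridization-control level and between the 2 of high level Nppb differed by 0.36 and -0.05.

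Rffl encodes rififylin, an endosome-associated ubiquitin ligase. Its transcript showed no detectable difference between the hearts. One of its probe sets read 6.00 ± 0.08 in Dahl S and 6.11 ± 0.07 in the congenic (SD, n = 3 each), a log2 difference of 0.11 (95% interval -0.04 to 0.27, adjusted p = 0.809 in limma). The other gave -0.02 (95% interval -0.19 to 0.15, adjusted p = 0.969), with means of 5.94 in Dahl S and 5.92 in the congenic. Both probe sets were dimmer than the median probe set, whose mean was 6.55, so the result rests on dim signal. With 1 array left out the first ran from 0.07 to 0.15 and the other from -0.08 to 0.04. Of the 23 listed chromosome 10 genes around Rffl, 14 were measured, and 0 of them were called by limma, either over all probe sets or adjusted over the list alone. At an unadjusted p under 0.05, Slfn9, a Schlafen family gene, was higher (0.19) and the DNA ligase gene Lig3 was lower (-0.19). As a group these genes did not move (mean 0.03, camera adjusted p = 0.393).

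The wider neighbourhood held Ccl5, the 11th measured gene past Rffl, and whether it lies in the Lewis segment is not known here. Among Rffl and the 20 measured genes on each side, 7 of 41 (17.1%) had an unadjusted p under 0.05, 4 higher and 3 lower, against 6.99% of all other genes (odds ratio 2.74, 95% interval 1.02 to 6.29; Fisher's exact p = 0.0227, adjusted p = 0.0454 over the 2 shares tested). They were the chemokine genes Ccl2 (0.32), Ccl4 (0.16) and Ccl6 (0.19) besides Ccl5, and Slfn9, Lig3 and Tefm (-0.14), of which the 4 outside the naming rule were chosen after their values had been seen. When adjusted over these 41 genes alone, 1 passed, Ccl5. The excess did not hold with any 1 array left out (odds ratios 0.991 to 2.33, exact p from 0.0596 to 1), nor without Ccl5 (2.35, exact p = 0.0584). Over chromosome 10 as a whole, 89 of 1213 genes (7.34%) had an unadjusted p under 0.05 against 906 of 12954 (6.99%) elsewhere (odds ratio 1.05, 95% interval 0.830 to 1.32, Fisher's exact p = 0.638). Without Dahl S array 1 the odds ratio was 0.788 (exact p = 0.0319), and without each of the other arrays it lay between 0.925 and 1.03.

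**Figure D2:**
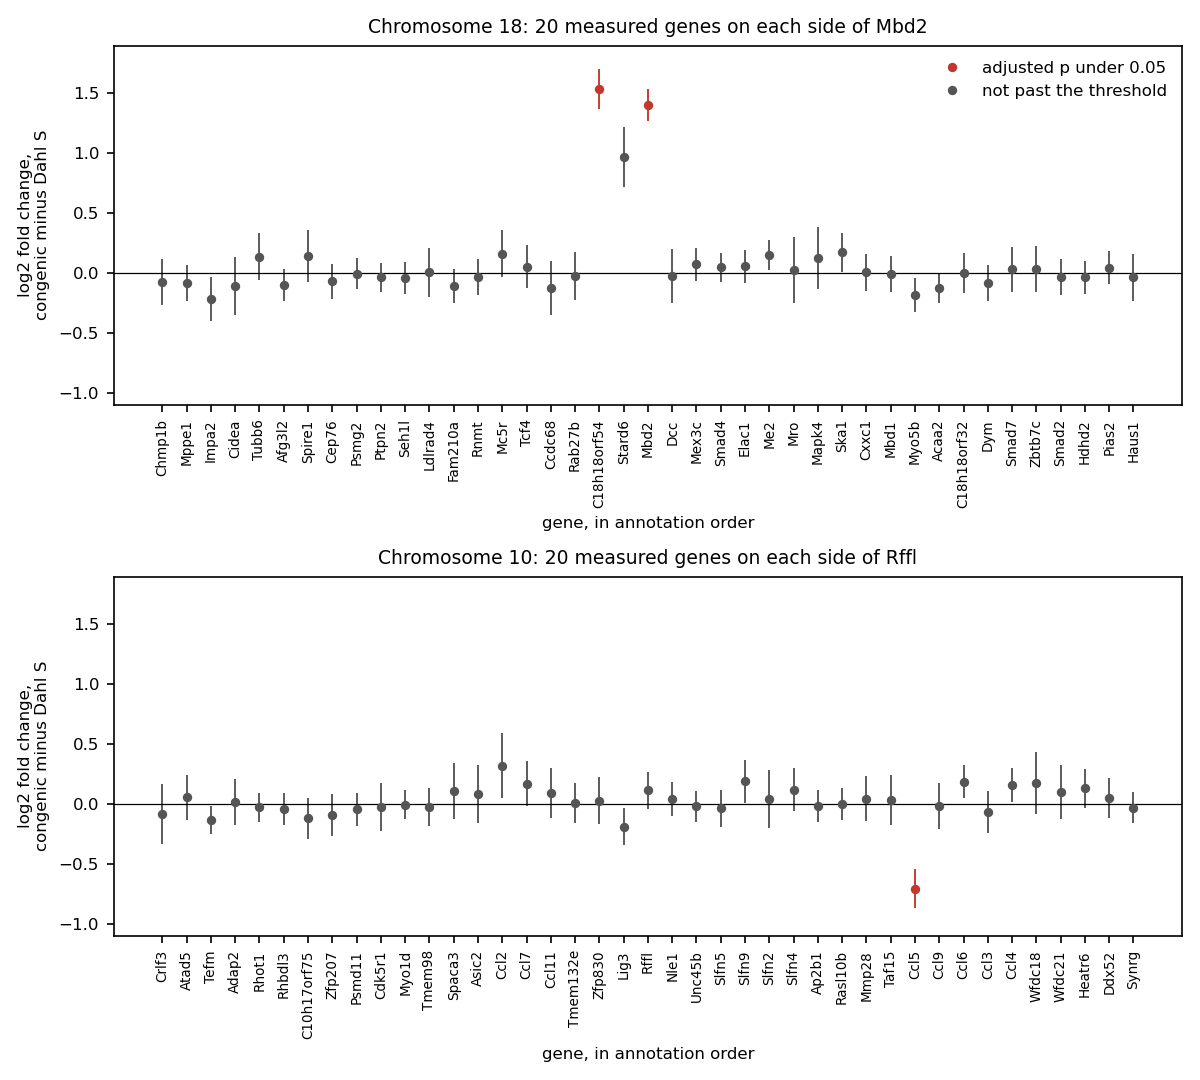
Log2 difference, congenic minus Dahl S, with its 95% interval for each measured gene in annotation order, for 20 genes on each side of Mbd2 on chromosome 18 (top) and of Rffl on chromosome 10 (bottom). Red points passed an adjusted p under 0.05. C18h18orf54, Stard6 and Mbd2 stand at 0.97 or above while the 38 genes around them stay between -0.22 and 0.17, and Ccl5 is the only red point around Rffl, at -0.71.

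Interferon-induced genes were higher as a group in the congenic heart. Of 26 measured genes in the interferon response list, 14 were higher and 1 lower at an unadjusted p under 0.05, and the mean log2 difference was 0.17 (camera adjusted p = 4.41e-11; adjusted p = 0.0604 with an estimated correlation). The correlation estimated for this list, 0.0098, was close to the preset 0.01. Correlation between its genes therefore does not account for the gap between these adjusted p. Irf7, the transcription factor that drives type I interferon production, had a log2 difference of 0.46 and Ifit3, an antiviral effector, of 0.47. Isg15 (0.32), Mx2 (0.31), Gbp2 (0.28) and the chemokine gene Cxcl10 (0.42), picked after their values had been seen, were higher too. The lower gene was Usp18 (-0.29), whose product removes Isg15 from proteins and damps interferon signalling. None of the 26 passed over all probe sets (0 called by limma), and 12 passed when adjusted over the list alone, 11 higher and Usp18 lower. The list medians were close together on the 3 Dahl S arrays (-0.09 on each, relative to each gene's mean over 6 arrays) and ran from 0.05 to 0.10 on the congenic arrays. This was the only list past the threshold in limma's fry (adjusted p = 0.0175).

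Cell cycle and matrix genes also rose as groups. In the cell cycle list 12 of 28 genes were higher and 0 lower at an unadjusted p under 0.05, with a mean of 0.19 (camera adjusted p = 7.28e-11; adjusted p = 0.250 with an estimated correlation). The microtubule-bundling gene Prc1 (0.50), the proliferation marker Mki67 (0.39), the spindle checkpoint gene Bub1b (0.34) and Ube2c (0.29) were the 4 that passed when adjusted over the list alone. In the extracellular matrix and fibrosis list 11 of 31 were higher and 0 lower, with a mean of 0.15 (camera adjusted p = 1.04e-10; adjusted p = 0.250 with an estimated correlation). The profibrotic matricellular gene Ccn2 (0.41), the collagen genes Col1a2 (0.39) and Col1a1 (0.24), Loxl1 (0.22) and Bgn (0.25) were the 5 that passed when adjusted over the list alone. The cardiac stress and hypertrophy list rose by a mean of 0.11 (camera adjusted p = 2.87e-04; adjusted p = 0.250 with an estimated correlation), with 3 of 21 genes higher, Ccn2, Myh7 and Timp1, of which Ccn2 passed when adjusted over the list alone. Ccn2 and Timp1 also belong to the matrix list, and other members are shared too. The rises of the stress and matrix lists are therefore not independent. Limma called 0 members of these 3 lists over all probe sets. Within the 4 arrays of low hybridization-control level and between the 2 of high level, the mean was 0.25 and 0.07 for cell cycle genes, 0.18 and 0.13 for interferon genes and 0.15 and 0.14 for matrix genes, and whether the levels differ was not tested. Matrix medians moved with those of the fibroblast markers, a list that shares 5 of its measured genes: on Dahl S arrays 1, 2 and 3 they were -0.12, -0.07 and -0.01 against -0.10, -0.07 and -0.01, and on congenic arrays 1, 2 and 3 they were 0.01, 0.13 and 0.08 against -0.02, 0.10 and 0.07. Cell cycle medians moved with those of the macrophage markers over the arrays. On Dahl S arrays 1, 2 and 3 they were -0.21, -0.09 and 0.00 against -0.19, -0.09 and 0.02 for macrophage markers, and on congenic arrays 1, 2 and 3 they were 0.02, 0.05 and 0.16 against 0.03, 0.02 and 0.14.

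Oxidative metabolism went the other way, by small amounts. The fatty acid oxidation list fell by a mean of 0.07 (camera adjusted p = 3.09e-05; adjusted p = 0.250 with an estimated correlation), with 3 of its 33 genes on the positive side. The oxidative phosphorylation list fell by 0.05 (camera adjusted p = 0.00456; adjusted p = 0.442 with an estimated correlation), with 2 of 37 genes on the positive side. Among single genes, Ppargc1a, the coactivator of mitochondrial biogenesis, had a log2 difference of -0.14, Acot1 of 0.22 and Cox7a1, a muscle isoform of a cytochrome c oxidase subunit, of -0.31, and these were the only members of both lists with an unadjusted p under 0.05. The Acot1 probe set was dim, with means of 3.94 in Dahl S and 4.16 in the congenic heart. The circadian clock list fell by 0.07 (camera adjusted p = 0.0356; adjusted p = 0.403 with an estimated correlation), with Hlf at -0.25 (-0.16 without congenic array 2) and Nfil3 at -0.14. Within the 4 arrays of low hybridization-control level and between the 2 of high level Hlf differed by -0.13 and -0.48. Limma called 0 members of the 3 lists, over all probe sets or adjusted over the list alone. The oxidative phosphorylation call was lost without congenic array 2 (camera adjusted p = 0.0517), and the circadian call without Dahl S array 2 (0.454) or congenic array 2 (0.126), its mean being -0.04 and -0.06 in these fits and -0.11 without Dahl S array 1. The circadian call was also lost with quantile normalization (0.0891), with the hybridization-control level as a block (0.0529) and within the 4 arrays of low level (0.111), and held in 10 of 18 alternative settings.

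Markers of several non-muscle cell types were higher in the congenic heart. Erythroid and blood markers had a mean of 0.20 (camera adjusted p = 8.55e-06; adjusted p = 0.250 with an estimated correlation), with Ahsp, the alpha-haemoglobin chaperone, at 0.40 (0.26 without Dahl S array 1) and the haem synthesis gene Alas2 at 0.36. Fibroblast markers had a mean of 0.14 (camera adjusted p = 1.12e-05; adjusted p = 0.403 with an estimated correlation), led by the same Col1a2 and Col1a1. Mesothelial and epicardial markers also had a mean of 0.14 (camera adjusted p = 0.00221; adjusted p = 0.250 with an estimated correlation), with the retinoic acid synthesis gene Aldh1a2 at 0.26 and Krt19 at 0.41 (0.26 without Dahl S array 3, and 0.23 within the 4 arrays of low hybridization-control level against 0.78 between the 2 of high level). Macrophage markers had a mean of 0.11 (camera adjusted p = 6.98e-05; adjusted p = 0.422 with an estimated correlation), with Adgre1 at 0.40 and Fcgr3a at 0.23. Endothelial markers had a mean of 0.05 (camera adjusted p = 0.0343; adjusted p = 0.536 with an estimated correlation), with Eng at 0.13 and Pecam1 at 0.14 (0.08 without Dahl S array 1). Limma called 0 genes of these 5 lists over all probe sets, and Aldh1a2 alone passed when adjusted over its list alone. The endothelial call was lost without any of 4 arrays (camera adjusted p from 0.0665 to 0.167), and held in 11 of 18 alternative settings, and its mean was 0.03 without Dahl S array 1. The macrophage mean was 0.05 without Dahl S array 1 and 0.19 without Dahl S array 3, and it was 0.21 within the 4 arrays of low hybridization-control level and -0.09 between the 2 of high level. The fibroblast mean was 0.17 and 0.07 in these, and the other 3 lists lay above 0 in both.

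**Figure D3:**
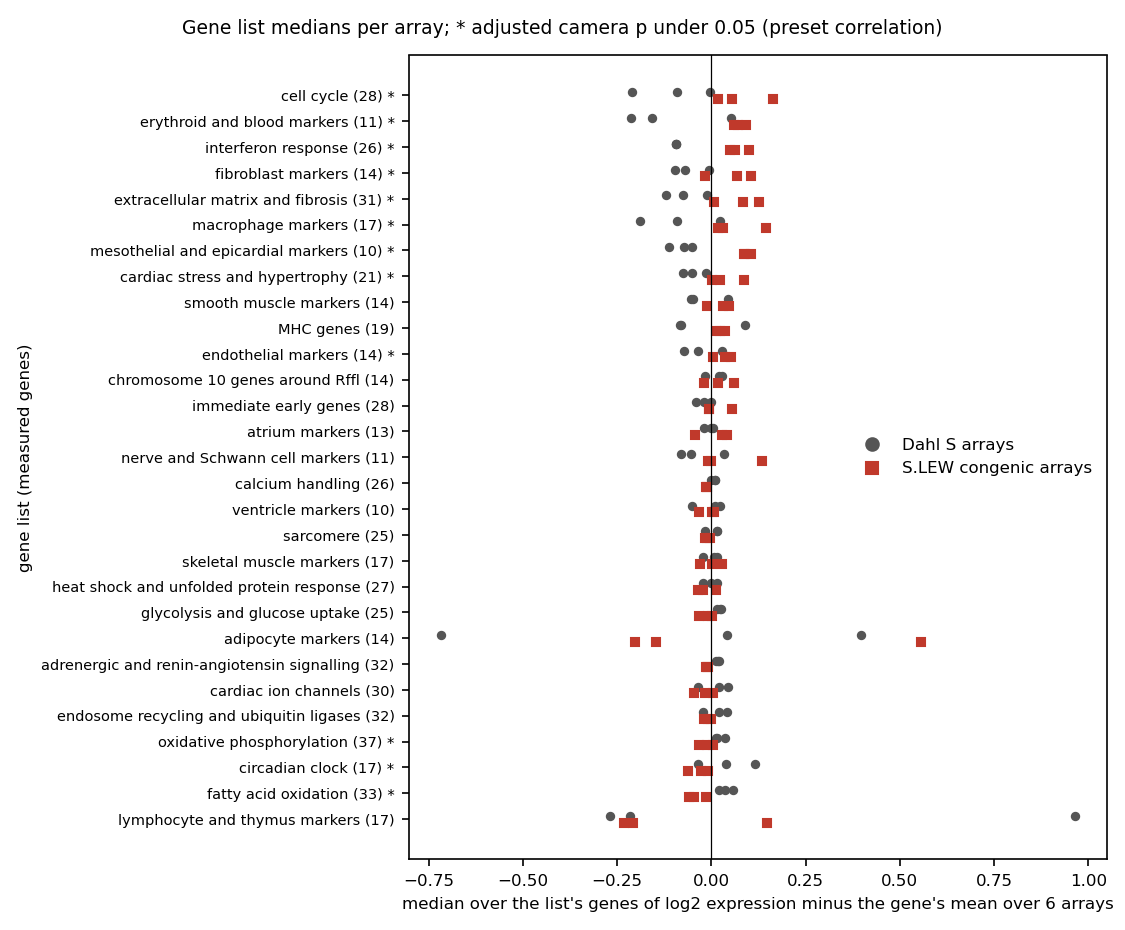
Median over each list's measured genes (number in parentheses) of log2 expression minus the gene's mean over the 6 arrays, for each Dahl S array (grey circles) and each congenic array (red squares). Lists are ordered by their median log2 difference, and a star marks an adjusted camera p under 0.05 at the preset correlation. The interferon medians of the Dahl S arrays coincide at -0.09 below congenic medians of 0.05 to 0.10, and the lymphocyte median of Dahl S array 3 stands apart at 0.97.

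The remaining lists did not pass. Immediate early genes had a mean of 0.04 (camera adjusted p = 0.0519), with Egr1 at 0.22 and Jun at 0.19 (0.12 without congenic array 3). MHC genes had a mean of 0.05 (0.115), with RT1-S3 at 0.17 and RT1-DMb at -0.18, and smooth muscle markers of 0.07 (0.115). Of 30 cardiac ion channel genes, 3 were higher and 3 lower at an unadjusted p under 0.05 and 0 passed over all probe sets or over this list alone, with Kcna5, a potassium channel of the atrial action potential, at 0.39, Cacna1h at 0.30 and Scn4b at -0.25, and a list mean of 0.00 (0.876). Adrenergic and renin-angiotensin genes had a mean of -0.02 (0.417), with the adrenergic receptor gene Adra1a at -0.27 and the mineralocorticoid receptor gene Nr3c2 at -0.18. The list of endosome recycling and ubiquitin ligase genes, the cellular setting of rififylin, had a mean of -0.03 (0.319), with Myo5b and Nedd4l both at -0.18. The means were -0.02 for calcium handling (0.342), glycolysis and glucose uptake (0.342) and the heat shock and unfolded protein response (0.482), 0.04 for atrium markers (0.342) and 0.02 for nerve and Schwann cell markers (0.393). For sarcomere genes (0.876), ventricle markers (0.939) and skeletal muscle markers (0.889) the means of 0.00, 0.01 and 0.00 had medians of the opposite sign (-0.02, -0.01 and -0.02), and camera's direction was down, up and up. Adipocyte markers (mean and median below 0, at 0.00 and -0.02, camera direction up, adjusted p = 0.992) and lymphocyte and thymus markers (mean -0.16, 0.349) varied more within the strains than between them. MHC genes passed without Dahl S array 3 (mean 0.12, camera adjusted p = 2.69e-05), as did smooth muscle markers (0.11, 0.0251), and both passed within the 4 arrays of low hybridization-control level (0.13, 3.94e-05 and 0.09, 0.0230). Smooth muscle markers also passed without congenic array 1 (mean 0.10, camera adjusted p = 0.0432), with quantile normalization (0.08, 0.0416) and with the hybridization-control level as a block (0.07, 0.0267), and immediate early genes without congenic array 1 (0.05, 0.0149) or 2 (0.05, 0.0488). The means were lower elsewhere: 0.02 for immediate early genes without congenic array 3, 0.03 for smooth muscle markers without Dahl S array 2, and for MHC genes 0.00462 without Dahl S array 1 and -0.12 between the 2 arrays of high level. Lymphocyte markers passed, lower in the congenic, without Dahl S array 2 (mean -0.34, camera adjusted p = 0.0468) or congenic array 1 (-0.37, 0.0222), but their mean was 0.22 without Dahl S array 3, 0.31 within the 4 arrays of low level and -1.09 between the 2 of high level. With 1 array left out, the mean ran from -0.30 to 0.27 for adipocyte markers and from -0.06 to 0.09 for nerve and Schwann cell markers. In the same fits it ran from -0.025 to 0.018 for ion channel genes and from -0.033 to 0.003 for the heat shock list. For the endosome list it ran from -0.046 to -0.016, for glycolysis from -0.034 to -0.013 and for atrium markers from 0.024 to 0.059. When adjusted over the list alone, 1 gene of the atrial list passed, Kcna5, and 1 of the skeletal muscle list, the fast myosin light chain gene Myl11 (0.39). The other list members named by the rule had limma adjusted p from 0.731 to 0.800. Higher were Trib3 (0.10), Prph (0.23), Cd52 (0.34), Lep (0.24), Acta2 (0.25) and Pdgfrb (0.17). Lower were Hspb1 (-0.11), Pgam2 (-0.14), Pdk1 (-0.13), Lmod2 (-0.16), Hrc (-0.15), Ppp1r1a (-0.24) and Ngfr (-0.27). So were Myl1 (-0.20), Irx5 (-0.17), Fgf12 (-0.18), Pnpla2 (-0.13), Ndufb6 (-0.09) and Gzma (-0.24).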

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

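The alternatives with the hybridization-control level, without the 3 chromosome 18 genes and without Ccl5 were chosen after the data had been seen, and the others were planned. The count of 11 called probe sets was 7 among probe sets with 1 gene, 5 with the replicate number as a block, 5 with the hybridization-control level as a block, 2 within the 4 arrays of low level, 0 with the ordinary variance (2074 at an unadjusted p under 0.05), 3 without the probe sets of Mbd2, Stard6 and C18h18orf54, and 5 to 6 with 1 array left out. It was 16 with eBayes trend and 16 with array weights, each holding the 11. Among the called probe sets outside Mbd2 and C18h18orf54, the 3 unnamed higher ones had the smallest unadjusted p. The 3 calls left without the chromosome 18 genes were thus these, and all 5 lower calls, Ccl5 among them, were lost there. The 3 unnamed probe sets have no chromosome here, so whether they belong to the same block is not known. Same-numbered arrays of the strains did not deviate together (correlations of -0.07, -0.06 and -0.18 between their deviations from the strain means), so the numbers were not used as pairs; all 5 calls with the replicate block were among the 11. The calls on Mbd2 held in 16 of 17 settings, while those on Cda, Ccl5 and Lmod3 held in 8, 7 and 7 of 17 and that on Asb5 in 5 of 16, with adjusted p up to 0.386, 0.396, 0.396 and 0.462. The count of 12 called lists was 0 with an estimated correlation, 1 with fry and 10 to 14 with 1 array left out; apart from the estimated correlation and fry, 9 of the 12 kept their call in all 18 settings. The circadian call was lost in 8 of the 18, among them dim probe sets left out (adjusted p = 0.223), the ordinary variance (0.0740) and the mean of a gene's probe sets (0.116), and the endothelial call in 7, among them array weights (0.314), the replicate block (0.0714) and the 4 arrays of low level (0.235). Lists beyond the 12 passed with dim probe sets left out (immediate early genes 0.0150, MHC genes and smooth muscle markers 0.0280 each), array weights (MHC genes 0.0153, smooth muscle markers 0.0228), eBayes trend and the ordinary variance (immediate early genes 0.0388 and 0.0449). The odds ratio for chromosome 10 crossed 1 without passing the test with dim probe sets left out (0.947), eBayes trend (0.999), array weights (0.986), the replicate block (0.953), an unadjusted p under 0.01 (0.956), the hybridization-control block (0.975) and the 4 arrays of low level (0.981), and it ran from 0.788 (without Dahl S array 1, exact p = 0.0319, reversed) to 1.03 with 1 array left out. The odds ratio around Rffl lost its call with quantile normalization (1.87), eBayes trend (1.79), the ordinary variance (1.59), the replicate block (1.38), an unadjusted p under 0.01 (1.59), 10 genes on each side (2.21), the 4 arrays of low level (2.54), without Ccl5 (2.35) and with any 1 array left out (0.991 to 2.33, the lowest without congenic array 3). The mean of the chromosome 10 list stayed uncalled, from 0.01 to 0.04 with 1 array left out. The cause of these changes was not tested.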

Other observations

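The pools differed in tissue makeup within the strains. Dahl S array 3 carried far more lymphocyte transcript than the other arrays, with Cd3e of the T cell receptor complex at 8.41 (log2) against 5.96 to 7.49 on the others, the B cell gene Ms4a1 at 7.15 against 4.59 to 5.24 and Ptprc at 8.80 against 7.37 to 7.78. Congenic array 1 had the next highest Cd3e, 7.49, with Ms4a1 at 4.61. Adipocyte genes varied in both strains: Plin1 ran from 7.37 to 9.27 and Adipoq from 6.99 to 8.59 among the Dahl S arrays, and Plin1 from 7.77 to 8.98 and Adipoq from 7.13 to 8.44 among the congenic arrays. Chromosome 18 had the highest share of genes with an unadjusted p under 0.05 of the 21 chromosomes compared, 39 of 328 or 11.9% (Fisher's exact p = 0.00136, adjusted p = 0.0285 over the 21). Without Mbd2, Stard6 and C18h18orf54 it was 36 of 325 (11.1%, exact p = 0.00576, adjusted p = 0.121), 13 higher and 23 lower. This chromosome was singled out after its values had been seen.

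The tests of explanations that follow were chosen after the results had been seen, except the regroupings of the 6 arrays, which were planned. The 6 arrays can be parted into groups of 3 in 10 ways, too few for a share under 0.05. The real grouping called 11 probe sets (highest other 0), 12 lists (highest other 11) and 7 genes with an unadjusted p under 0.05 around Rffl (highest other 3), and in each case 1 grouping, the real one, reached its count. The grouping with 11 lists set Dahl S arrays 1 and 2 and congenic array 1 against the rest. For 3 of the 12 lists another grouping gave a larger mean than strain: 0.17 against 0.11 for macrophage markers (3 of 10 groupings as large, the real one included), 0.09 in size against a fall of 0.07 for the circadian clock list (3 of 10) and 0.06 against 0.05 for endothelial markers (2 of 10). For matrix genes another grouping reached 0.14 against 0.15, and for fibroblast markers 0.13 against 0.14. The hybridization-control level was high on 1 array of each strain, so that a shift with this level alone would cancel between the strains.

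C18h18orf54, Stard6 and Mbd2 are 3 adjacent measured genes on chromosome 18, higher by 0.97 to 1.85, although the strain is named for a segment of chromosome 10. A gain or loss that changes each gene's dose alike cannot be told apart from other causes, since the 2 brighter probe sets differed by 0.13 (SE 0.09) while the smallest and the largest of the 4 differences were 0.88 apart (SE 0.15), both on dimmer probe sets. Sequence variants under the probes also stay open. Of the 4 probe sets, 0 had a difference under 0.5, but the genes were singled out as higher, so this count cannot decide. Probe-level values were not analysed here. As a hypothesis, a strain difference at this block on chromosome 18 may lie in DNA copy number, in regulation or in the probes' match.

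Ccl5 lies 11 measured genes past Rffl and was lower on all 3 congenic arrays. A common fall across the whole neighbourhood of Rffl is argued against by the median of its other genes, 0.0223. Changes in both directions would not move this median. At an unadjusted p under 0.05, 4 genes of the neighbourhood were higher and 3 lower, Ccl5 among the latter. Fewer lymphocytes as a whole are argued against by the 4 arrays left without the most lymphocyte-rich one of each strain, Dahl S array 3 and congenic array 1: there the 17 lymphocyte genes had a mean difference of 0.00 (SE 0.04 over genes), while Ccl5 differed by -0.76 (SE 0.09). The SE over genes is not comparable with that of Ccl5, since it does not measure the spread between arrays and these genes move together (estimated correlation 0.629). The arrays left out were picked by this list, which favours a list mean near 0. On Dahl S array 3, where the lymphocyte median was higher by 1.18 than on the next Dahl S array, Ccl5 read 7.95 against 7.96 and 8.02. A subset of lymphocytes and a Lewis allele were not tested and stay open. The 2 members of the lymphocyte list with the smallest unadjusted p went opposite ways. Gzma was lower (-0.24, limma adjusted p = 0.731), on a dim probe set with means of 4.14 in Dahl S and 3.90 in the congenic. Cd52 was higher (0.34, limma adjusted p = 0.736).

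For the interferon list, more macrophages are argued against by the 3 Dahl S arrays alone, whose interferon medians spanned 0.00557 of the span of their macrophage medians. On congenic arrays 1, 2 and 3 the interferon medians were 0.10, 0.05 and 0.06 against 0.03, 0.02 and 0.14 for macrophage markers. There the interferon medians did not coincide, and the spans were not tested. The interferon mean of 0.17 compares with at most 0.08 under the other groupings of the arrays. For the cell cycle list, neither 1 low Dahl S array nor more macrophages can be set apart from strain: the mean without Dahl S array 1 was 0.14 against 0.19 with it, and the cell cycle medians of the Dahl S arrays spanned 0.994 of the span of their macrophage medians. Under another grouping the cell cycle mean reached 0.17. A slightly higher interferon tone in the congenic heart is thus a hypothesis that the test on the Dahl S arrays left standing, found and tested on the same 6 arrays.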
